A study of Mus musculus with 207 samples.

How the data were processed

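Islet cells of male mice aged 3 or 26 months were captured one by one on a Fluidigm C1 microfluidic chip, and cDNA was made and amplified with the SMARTer chemistry and turned into libraries with Nextera XT, per the labels' protocols. These libraries carry no molecular identifiers in the sources used here and their strand handling is not given, so reads of overlapping genes on opposite strands, such as mt-Nd6 and its neighbours, cannot be told apart. The submitters' processing notes name the genome build GRCm38 (mm10), CASAVA 1.8.2 and FastQC. The aligner, the counting program and the annotation are not given in the sources used here. The authors deposited 1 table of TPM values with a column for each of the 207 cells, and its columns were matched to the samples by their titles; 0 columns were left unused. TPM scales each cell to a total of 1000000 after division by transcript length, so the deposited values hold no depth and a gain in one abundant transcript lowers all others. The precision behind a single TPM value is therefore unknown, and detected genes per cell were the only sign of depth.

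Rows are NCBI Gene numbers. Of 44448 rows, 39725 were matched to a symbol in a RefSeq gene table of assembly GRCm38.p6, and the 4723 others held a mean of 928 TPM per cell. Coordinates are those of that table, whose build is the one in the submitters' notes. No cell was left out of the main values, no doublet caller was run, and no 2 cells were identical. All cells were grouped by the age in their labels. The labels call every cell a beta cell and give no clusters, and no clustering was made.

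The age difference of a gene is log2((mean TPM of old cells + 1)/(mean TPM of young cells + 1)), which understates the differences of low genes. A gene was called detected in a cell at TPM 1 or above. No p-value, standard error or count of changed genes was computed, since each age is 1 sample; counts of list members at a 1.5-fold difference describe size only. Before the data were examined, 17 gene lists, 11 lists of cell type markers, the rule for named genes and the alternatives were fixed. A list's value is the median over its members with a mean TPM of 1 or above at either age, set against 10000 random lists of the same size drawn from 20 bins of mean expression. Named genes were taken by rule from genes with a mean TPM of 10 or above at either age, detected in at least 25% of cells of the age with the higher mean, and with the same sign for the ratio of means, the difference of mean log2(TPM+1) and the difference in share of cells. From these came the 12 highest and 12 lowest ratios and the 5 largest differences of share each way, leaving out gene models without a proper symbol. The 2 highest and 2 lowest members of each list, 20 genes fixed by name and the cell type markers with a mean TPM of 10 or above were added, of which the text gives examples. Some genes that this rule named are not used here, and the counts of named genes under alternatives leave them out.

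Runs were found after the data had been seen, from the order of the cell numbers in the sample titles. Least-squares change points were placed within each age on 4 standardised measures (detected genes, mitochondrial coding TPM, mitochondrial rRNA and tRNA TPM, and the TPM of 5 abundant nuclear noncoding RNAs, among them Malat1), with a shortest run of 8 cells and a penalty multiplier of 2. The same boundaries came out with a multiplier of 1. With 3, the young cells 55 to 138 formed 1 run. On 5 principal components and a multiplier of 1, the young boundaries were the same and the old cells 191 to 207 formed 1 run. With multipliers of 2 and 3 on the components, the young cells 55 to 138 and the old cells 159 to 207 each formed 1 run. The old runs of cells 191 to 207 and 159 to 207 found on the components hold cells of both kinds. The 2 kinds of runs were split at the widest gap between the runs' log2 mean mitochondrial rRNA and tRNA.

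The per-gene ratio, the list percentile and the run boundaries were tested on simulated data. This test was written after the first values had been computed on the deposited table. Values of each gene were drawn from the young cells for 207 simulated cells, 200 genes of the 44448 were changed by known folds, and the median recovered log2 ratios of old over young were 0.58, 0.98, 2.04 and 3.02 for genes made 1.5, 2, 4 and 8 times higher and -0.51, -1.01, -1.79 and -2.75 for genes made lower by those folds. In the simulated list comparison on 11694 genes, a list of 20 genes made 2-fold higher lay at the 100th percentile and a list of 20 unaltered genes at the 67.4th. Each gene was drawn on its own, so genes that rise and fall together in cells or runs were not simulated. The percentiles of lists with such genes were therefore not checked by this test. Of 300 simulated run boundaries, 260 were found within 2 cells, and none was called in 100 series without one. These boundaries lay where they had been found in the young cells, with all 4 measures shifted by 1.5 SD in independent noise. The shorter series of old cells and boundaries at which only some measures shift were not simulated. The runs of the old cells were therefore not checked by this test. Alternatives concerned the pseudocount, the mean, the scaling, filters on genes, the choice of cells and, added after seeing the data, the runs. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.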

Results

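Single cells from the pancreatic islets of male mice were sequenced at 2 ages, 3 months (young, 138 cells) and 26 months (old, 69 cells). The labels call each of them a beta cell, the islet cell that makes insulin. Each cell was captured on a microfluidic chip, its RNA was copied and amplified on the chip, and its expression was deposited as TPM, a unit scaled for gene length and total, so that every cell sums to the same total and read depth is unknown. A young cell had a median of 4291.5 genes at TPM 1 or above (range 1604 to 6654), and an old cell had 4078 (range 1916 to 6007). The labels name no animal for any cell. Cells are not replicates, each age therefore counts as 1 sample, and the comparison of the ages has no test and no replicate check. Values are means over cells with the SD between cells, and 95% Clopper-Pearson intervals of shares of cells cover counting error only.

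Insulin transcripts made up most of the TPM of the median cell at both ages. Ins1 and Ins2 together took a median of 54.5% of TPM in young (range 15.7 to 78.7%) and 51.7% in old cells (range 25.8 to 69.9%). Ins2 was at 495521 ± 91955 TPM in young and 475818 ± 83128 TPM in old cells, a log2 ratio of old over young of -0.06, and Ins1 at 49802 ± 16516 TPM in young and 43428 ± 15544 TPM in old cells (-0.20). Iapp, which encodes the peptide amylin that is released with insulin, differed by -0.0037, with 0.15 in the low-kind and -0.26 in the high-kind runs. Reads of Ins1 and Ins2 can be shared, since the genes are close copies, so their separate values are less certain than their sum.

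Cell numbers in the labels ordered the cells into stretches with different technical character, which bears on every comparison below. Along the cell numbers, the count of detected genes, the share of TPM in mitochondrial coding genes, the share in mitochondrial rRNA and tRNA and the level of abundant nuclear noncoding RNAs shifted at a few places. Not all of these measures shifted at each place. These shifts split the young cells into 4 runs (cells 1 to 39, 40 to 54, 55 to 86 and 87 to 138) and the old cells into 4 runs (cells 139 to 158, 159 to 190, 191 to 199 and 200 to 207). Median detected genes were 3944, 2320, 4226 and 5104.5 in the young runs and 4570.5, 3633.5, 3554 and 3776 in the old runs. Runs were sought within each age, so each holds 1 age by construction, and a run and its age cannot be told apart. Mean mitochondrial rRNA and tRNA, however, divided the runs into 2 kinds that each hold both ages. In the low kind (cells 1 to 54 and the old cells 159 to 190 and 200 to 207; 54 young and 40 old cells) it was 0.373% of TPM in young and 0.264% in old cells, and in the high kind (84 young and 29 old cells) it was 1.28% and 2.24%. The long noncoding RNA Malat1 followed the kind and not the age, at 313 and 309 TPM in young and old cells of the low kind and 3231 and 2642 TPM in the high kind. Malat1 is among the abundant nuclear noncoding RNAs that helped to place the run boundaries, so it is not separate evidence for the runs. Values within the low kind and the high kind are therefore given beside the pooled ones for the lists and for many of the genes. Both the runs and the kinds were defined after the data had been seen. Cell 200 had a log2 mitochondrial rRNA and tRNA of 13.82, within the 12.21 to 15.89 of cells 191 to 199. The other cells of its run had 9.18 to 11.63. A run had to hold at least 8 cells, so the boundary could not be placed after cell 200. It is counted in the low kind, and values with it moved to the high kind are not given. Single young cells of the low kind lay as high, such as cell 38 at 13.88.

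**Figure D1:**
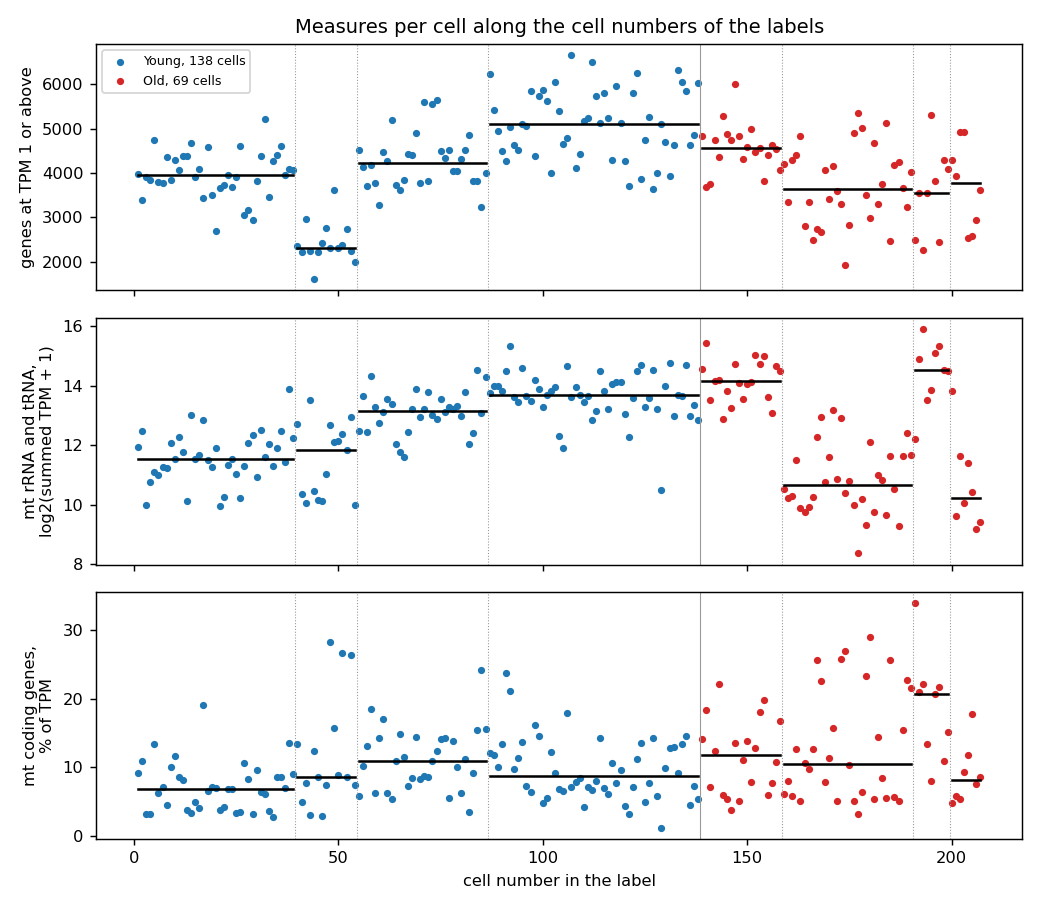
Number of detected genes (top), mitochondrial rRNA and tRNA on a log2 scale (middle) and the percentage of TPM in mitochondrial coding genes (bottom) for each of the 207 cells along the cell numbers of the labels. Points are cells, young in blue and old in red, horizontal lines are run medians, dotted lines are run boundaries and the solid vertical line separates the ages; the run of cells 40 to 54 has the lowest median of detected genes, 2320.

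The first question was whether beta cells of the 2 ages differ in the genes that define the cell. With all cells pooled, most of them were close, and less so within the kinds. The list of insulin processing and granule genes had a median log2 ratio of 0.03, with 21 of its 23 measured members within 1.5-fold. Within the low and high kinds its medians were -0.16 and -0.05, and 7 and 8 of the members differed by 1.5-fold or more. Sytl4, which helps to move granules, was among the lowest at 89.4 against 53.2 TPM (young against old). Beta-cell transcription factors had a median of 0.10 (15 genes, 3 at least 1.5-fold higher and 1 at least 1.5-fold lower), at the 82.9 percentile of 10000 expression-matched random lists. Their medians were -0.11 and 0.17 in the low and high kinds, with 5 genes lower and 3 higher by that size in the low kind and 2 lower and 6 higher in the high kind. Pdx1, a main regulator of insulin transcription, was at 7.44 ± 18.9 TPM in young and 13.8 ± 31.0 TPM in old cells and was detected in 43.5% of cells at both ages. Neurod1 was at 30.5 against 30.6 TPM and Nkx6-1 at 11.1 against 8.99 TPM, with -1.76 in the low-kind and 0.70 in the high-kind runs. Mafa was listed near 0 at both ages (0.0239 against 0.395 TPM), and no direction was read from it. A loss of its reads in mapping or annotation was not excluded, so this value does not show that the gene is silent. The hormone gene Ucn3, a marker of mature beta cells, was at 522 ± 533 TPM in young and 798 ± 849 TPM in old cells (0.61), with 0.50 in the low-kind and 0.71 in the high-kind runs.

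Genes of glucose sensing and secretion coupling had a median of -0.13 (16 genes), with -0.43 and -0.02 in the low and high kinds. The glucose transporter gene Slc2a2 was at 159.5 against 182 TPM, with opposite directions in the kinds, -0.80 in the low-kind and 0.87 in the high-kind runs. Glp1r, which encodes the receptor of the incretin GLP-1, was lower in old cells at 11.7 against 4.12 TPM (-1.31), with -1.35 in the low-kind and -1.10 in the high-kind runs, but it was -0.65 without the old cells 159 to 190 and -0.67 as a difference of mean log2(TPM+1). The fatty acid receptor gene Ffar1 was also lower (-1.42), but 1 cell held 79.2% of its young total and 93.5% of its old total. Genes normally kept low in beta cells (7 measured) had a median of 0.49 and genes of immature endocrine cells (8 measured) one of 0.30. Both medians had opposite signs in the low and high kinds, at 0.75 and -0.52 for the former and 1.09 and -0.32 for the latter, and each turned negative when the old cells 159 to 190 were left out (-0.64 and -0.18).

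**Figure D2:**
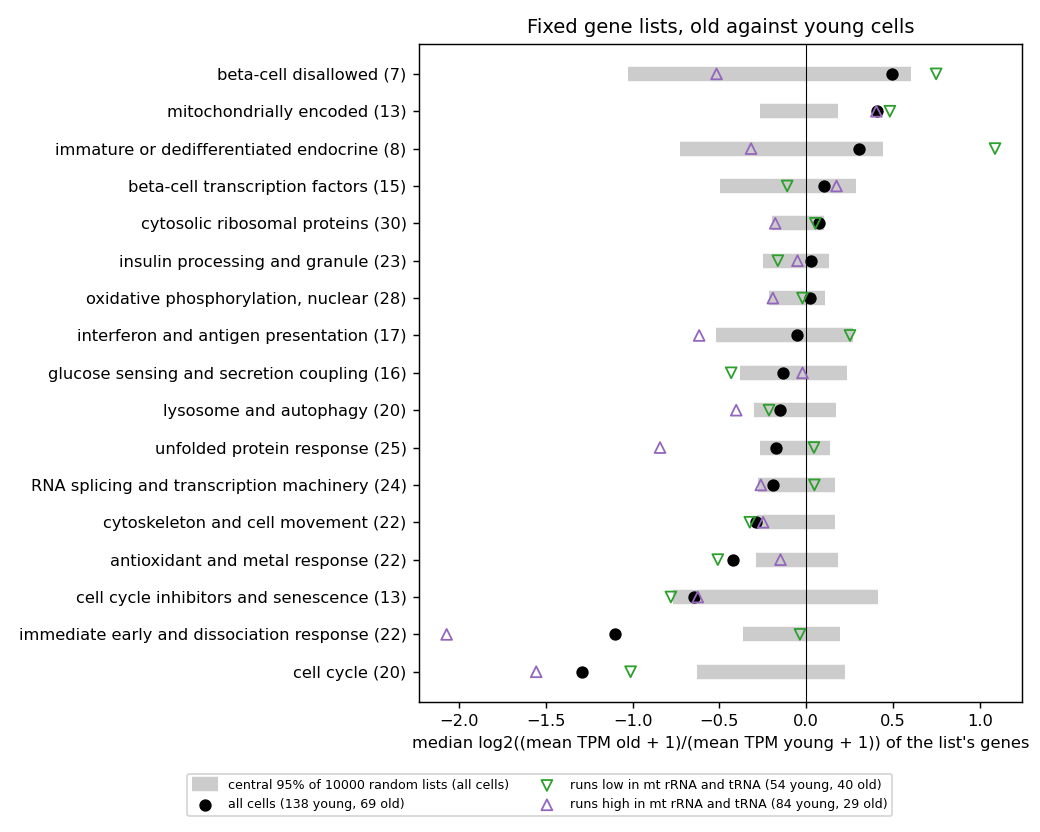
Median log2 ratio of old over young for the 17 gene lists fixed before the data were examined, with the number of measured genes in brackets. Black points use all cells, open triangles the runs of the low (down) and high (up) kind, and grey bars span the central 95% of 10000 random lists matched on expression; the mitochondrially encoded genes lie at 0.41 with all cells and at 0.48 and 0.40 in the 2 kinds.

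Hormones of other islet cells differed between the ages by larger log2 ratios than the beta-cell hormones did. The beta-cell hormones are far more abundant within a fixed total, so these sizes are not a like comparison. Whether the low levels of the other hormones in most cells were made by the cell itself or carried over from other cells was not tested. Sst, the delta-cell hormone somatostatin, was higher in old cells at 71.1 ± 125 TPM in young and 207 ± 374 TPM in old cells (1.52). Ppy and Pyy, which encode pancreatic polypeptide and peptide YY, were higher too, at 42.9 ± 81.5 TPM in young and 87.5 ± 146 TPM in old cells and at 24.2 ± 67.1 TPM in young and 95.4 ± 288 TPM in old cells. Gcg, the alpha-cell hormone glucagon, was lower at 86.6 ± 95.9 TPM in young and 30.6 ± 48.5 TPM in old cells (-1.47). These directions held in both kinds of runs, with log2 ratios in the low and high kinds of 1.49 and 1.56 for Sst, 0.70 and 1.42 for Ppy, 2.98 and 1.19 for Pyy and -0.92 and -1.98 for Gcg. Run means overlapped between the ages for Sst, Ppy and Gcg. For Pyy they ran from 6.21 to 31.8 TPM over the 4 young runs and from 52.9 to 277 TPM over the 4 old runs, but 1 old cell with 2101 TPM held 31.9% of the old total. Without it, the mean of its run of 8 cells was 16.0 TPM, within the range of the young runs, and the log2 ratio of Pyy was 1.41 over all cells and 2.11 in the low kind. No young cell had Gcg, Sst, Ppy or Pyy at TPM 1000 or above (0 of 138, upper bound 2.64%), against 7 of 69 old cells (10.1%, 4.18 to 19.8%), 5 of 40 in the low kind and 2 of 29 in the high kind. Of these, 6 carried Sst and 1 carried Pyy. Without the 6 cells with Sst at that level, the log2 ratio of Sst was 0.46, a setting that leaves out cells by the value compared. Other fixed delta-cell markers with a mean TPM of 10 or above did not follow Sst. Rgs2 was at -1.83 (-1.15 and -1.96 in the low and high kinds) and Pdyn at -0.38 (1.52 and -0.67). Sst lies on chromosome 16, 23889573 to 23891342, Ppy on chromosome 11, 102099931 to 102101319, Pyy beside it from 102106676 to 102107832, and Gcg on chromosome 2, 62474530 to 62483653 (GRCm38.p6).

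Protein-coding transcripts of the mitochondrial genome were higher in old cells. Its 13 protein-coding genes, all parts of the respiratory chain and ATP synthase, had a median log2 ratio of 0.41, above all 10000 random lists, and 11 of the 13 were above 0. Mitochondrial genes such as mt-Co1 and mt-Co3 are read from the same long transcript, so the members are not independent. Random lists of separately read genes do not show how far such a median can move. The 13 genes took a mean of 9.53% of TPM in young (SD 5.11) and 12.9% in old cells (SD 7.38). Mt-Nd4 was at 4938 ± 3979 TPM in young and 9599.9 ± 9322 TPM in old cells (0.96) and mt-Cytb at 11843 ± 6500.1 TPM in young and 17348 ± 10125 TPM in old cells (0.55), while mt-Nd6 was at -0.20 and mt-Co1 at -0.08. The median was 0.48 and 0.40 in the low and high kinds, with 12 of the 13 genes above 0 in both. Mitochondrial rRNA and tRNA did not share this direction in both kinds. They took 0.373% of TPM in young and 0.264% in old cells of the low kind, and 1.28% and 2.24% in the high kind. Nuclear genes of oxidative phosphorylation had a median of 0.02, and none of the 28 differed by 1.5-fold with all cells pooled. Their medians in the low and high kinds were -0.02 and -0.19. Mean log2(TPM+1) of the mitochondrial genes per run overlapped between the ages in the low kind (11.28 and 11.59 in young, 11.46 and 11.82 in old runs) and not in the high kind (12.04 and 12.07 in young, 12.20 and 12.90 in old runs). Some mitochondrial reads can be shared with nuclear copies, since the pseudogene Gm10925 was listed at 13369 against 17718 TPM.

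Immediate early genes are switched on within minutes of a stimulus or of tissue dissociation. They were fixed in 1 list with other dissociation response genes, such as the heat-shock gene Hspa1b, and the whole list is called immediate early genes here. It was lower in old cells when all cells were pooled. The list had a median log2 ratio of -1.10, below all 10000 random lists, and 17 of its 22 genes were at least 1.5-fold lower and none was at least 1.5-fold higher. Genes that rise together in the same cells are not allowed for in the random lists. Btg2, an antiproliferative gene, was at 256 ± 309 TPM in young and 65.0 ± 120.1 TPM in old cells (-1.96; chromosome 1, 134074865 to 134079155). The phosphatase gene Dusp1 was at 115 ± 165 TPM in young and 52.3 ± 133 TPM in old cells and was detected in 72.5% of young (64.2 to 79.7%) and 36.2% of old cells (25.0 to 48.7%), and the nuclear receptor gene Nr4a1 in 61.6% of young (52.9 to 69.7%) and 27.5% of old cells (17.5 to 39.6%). Among members chosen after their values were seen, the transcription factor genes Fos, Egr1 and Jun were at 557 against 191 TPM, 300.2 against 137 TPM and 46.2 against 12.4 TPM. Gadd45g and Gadd45b, at -0.02 and 0.21, were the highest members. The difference was carried by 1 kind of run: the median was -0.04 and -2.07 in the low and high kinds. Without the young cells 55 to 86 it was -0.33, the log2 ratio of Jun was -0.37 against -1.81, and that of Hspa1b, whose reads can be shared with its copy Hspa1a, was 1.38 against -2.22 with all cells. Run means of Btg2 ran from 133 to 450.0 TPM over the 4 young runs and from 30.5 to 82.0 TPM over the 4 old runs, and its log2 ratios in the low and high kinds were -1.42 and -2.56. Without 1 young cell with 1588 TPM, the mean of the young cells 40 to 54 was 29.4 TPM, so that the ranges of the ages overlapped, and the log2 ratio over all cells was -1.91.

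**Figure D3:**
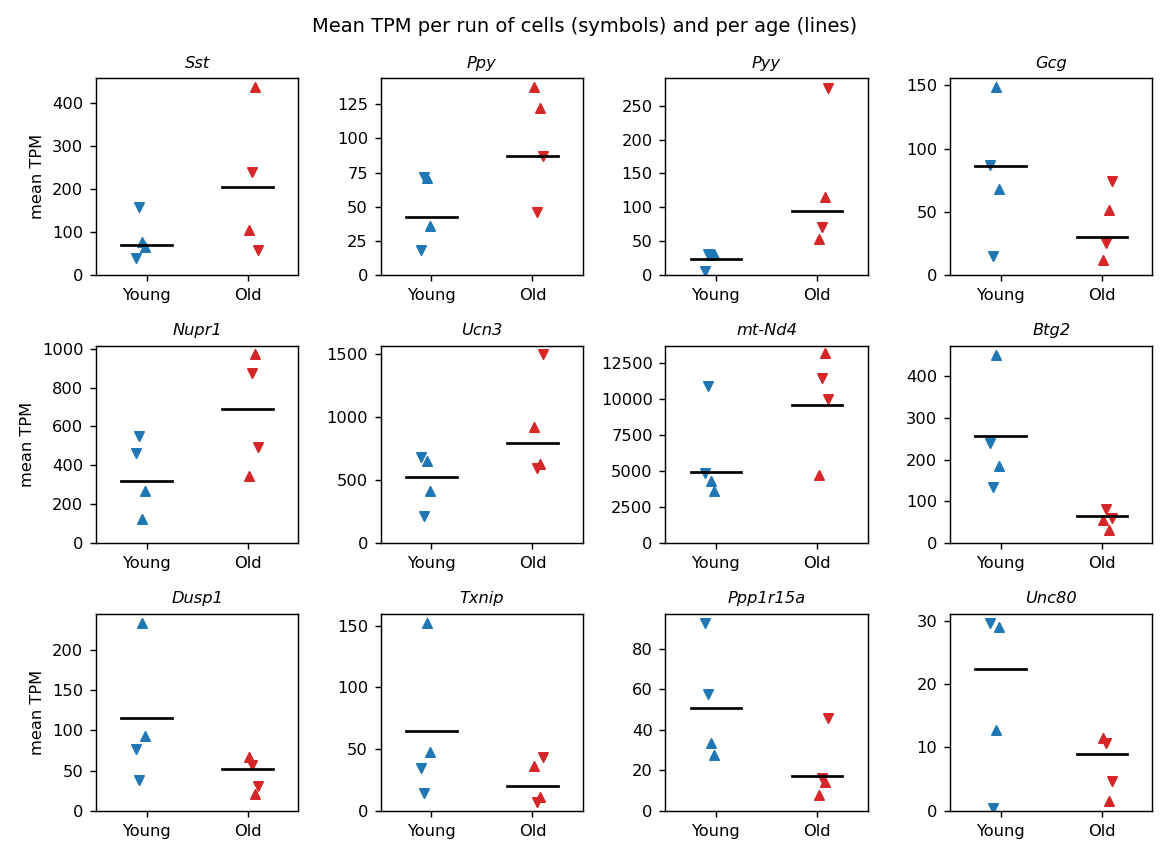
Mean TPM of 12 named genes in each run of cells, with 4 young runs in blue and 4 old runs in red (vertical axes in TPM, from 0). Triangles pointing down and up are runs of the low and high kind and black lines are the means over all cells of an age; the highest run mean of Pyy, 277 TPM, and the lowest young one of Btg2, 133 TPM, each rest on 1 cell.

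The medians of the antioxidant and the unfolded protein response lists were negative when all cells were pooled, though single members differed. Antioxidant and metal response genes had a median of -0.42, at the 0.0600 percentile of random lists, with 9 of 22 genes at least 1.5-fold lower and none at least 1.5-fold higher. Txnip, a glucose-induced inhibitor of thioredoxin, was at 64.9 ± 146 TPM in young and 20.5 ± 54.0 TPM in old cells (-1.62) and the glutathione peroxidase gene Gpx3 at 33.6 against 11.3 TPM. Without the young cells 55 to 86, the log2 ratio of Txnip was -0.88. The log2 ratios in the low and high kinds were -0.98 and -1.57 for Txnip and -0.11 and -1.76 for Gpx3, and the list's medians -0.51 and -0.15, at the 1.92 and 23.3 percentiles of random lists. Its mean log2(TPM+1) lay between 2.56 and 3.48 in the old runs, inside the 1.99 to 3.59 of the young runs. Unfolded protein response genes had a median of -0.17, with 0.04 and -0.84 in the low and high kinds, so the pooled value hid a difference between the kinds. Ppp1r15a, a phosphatase subunit gene of the integrated stress response, was lower at 50.6 ± 135 TPM in young and 17.0 ± 43.8 TPM in old cells, with -1.86 in the low-kind and -1.50 in the high-kind runs, while the chaperone gene Sdf2l1 was at 82.3 against 99.0 TPM, with 0.90 in the low-kind and -0.47 in the high-kind runs.

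Most cell cycle genes had lower means in old cells, though apart from Ccnd2, Cdk4, Ccnd1, Pcna and Ccnd3 they were detected in few cells of either age. The list's median log2 ratio was -1.29, below all 10000 random lists, with 18 of 20 genes at least 1.5-fold lower and medians of -1.01 and -1.55 in the low and high kinds. The replication gene Mcm4 was at 3.98 against 0.0455 TPM and was detected in 18.1% of young cells and in 0 of the 69 old cells, which allows a share of up to 5.21%. Top2a, Ccna2, Cdk1, Rrm2 and Ccnd3 were instead detected in a larger share of old cells, for example 5.07% against 8.70% for the cyclin gene Ccna2 and 19.6% against 31.9% for Ccnd3 (young against old). The chromatin gene Ezh2 was at 3.15 against 0.0110 TPM, and the proliferation marker Mki67 was near 0 at both ages (0.468 against 0.0153 TPM). Ccnd2, the main D-type cyclin of beta cells, was at 188 ± 121 TPM in young and 184 ± 177 TPM in old cells. Because most of the values rest on a few cells, the median was -0.17 as a difference of mean log2(TPM+1). On that scale the median over genes with a mean TPM of 10 or above was -0.20. Most list members lay below that level, so the 2 medians are not a like comparison. Whether the list was lower than genes of similar expression on that scale was not tested.

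Cell cycle inhibitors and senescence genes had a median of -0.65 (13 genes, 7 at least 1.5-fold lower and 3 at least 1.5-fold higher), with -0.78 and -0.62 in the low and high kinds. The pooled median lay at the 6.4 percentile of random lists and was -0.13 as a difference of mean log2(TPM+1). It was no longer negative with only members at TPM 10 or above, so its direction depended on members below that level. Cdkn2a, the gene of the senescence protein p16, was detected in 1 of 138 young and in 0 of 69 old cells. Cdkn1a was at 12.8 against 7.39 TPM and Igf1r, the receptor of insulin-like growth factor 1, at 11.2 against 11.3 TPM, with 0.86 in the low-kind and -0.62 in the high-kind runs. Glb1, the lysosomal beta-galactosidase gene, was at 4.42 against 22.5 TPM (2.12), but a smaller share of old than young cells detected it, and the log2 ratio was 1.099 without the old cells 159 to 190 (shares 18.8% and 20.3%).

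Several further genes were detected in a larger share of old cells. Nupr1, a stress-induced chromatin protein gene, was detected in 56.5% of young (47.8 to 64.9%) and 85.5% of old cells (75.0 to 92.8%) and had means of 321 ± 846 TPM in young and 689 ± 1213 TPM in old cells. Efna5, an ephrin ligand gene, was detected in 24.6% of young (17.7 to 32.7%) and 59.4% of old cells (46.9 to 71.1%). Tmem59l, Snhg11 and Pappa2 were detected in 29.7% against 63.8%, 20.3% against 52.2% and 21.7% against 50.7% (young against old). All 5 shares were higher in old cells within both kinds, for example 13.0% against 47.5% for Efna5 in the low kind and 32.1% against 75.9% in the high kind, which their choice by the pooled share favours. The log2 ratio of means of Tmem59l, 0.88, was 0.03 without the old cells 200 to 207, though it was 0.72 and 0.68 in the low and high kinds. The largest differences of share in the other direction were those of Ugt2b34, Dusp1, Unc80, Snord13 and Nr4a1. Ugt2b34, a glucuronosyltransferase gene, was detected in 46.4% of young (37.9 to 55.1%) and 10.1% of old cells (4.18 to 19.8%), and Unc80, a subunit gene of the sodium leak channel, in 81.9% of young (74.4 to 87.9%) and 46.4% of old cells (34.3 to 58.8%).

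By ratio of means among genes that passed the filters for naming (a mean TPM of 10, detection in 25% of cells, equal signs of 3 measures and a proper symbol), the 12 highest were Spp1, H4c8, Tmem216, Gnb5, Utp4, Commd5, Jmjd8, Pyy, Emd, Utp6, Prpsap2 and Grtp1, from 2.74 for Spp1 to 1.68 for Grtp1. Spp1, the gene of the secreted protein osteopontin and 1 of the fixed ductal markers, was at 36.6 ± 161 TPM in young and 251 ± 1003 TPM in old cells, and 1 old cell held 37.9% of the old total. It was higher in the low kind only (3.38 in the low-kind and -0.43 in the high-kind runs). The other 11 of these 12 had the same sign in both kinds, and 6 of the 12 were at least 1.5-fold higher in both, among them Gnb5 (2.16 and 2.31). The 12 lowest were Ifngr1, Ugt2b34, Cars, Etfrf1, Spryd7, Gpr89, Tmem231, Hnrnpm, Stim2, Gdap2, Tbc1d23 and Fuca2, from -4.15 for Ifngr1 to -2.32 for Fuca2. Ifngr1, a subunit gene of the interferon gamma receptor, was at 27.9 ± 182 TPM in young and 0.627 ± 1.90 TPM in old cells, with 47.5% of the young total in 1 cell. Among these 12, 11 were at least 1.5-fold lower in both kinds, and the exception was Gpr89 (-5.003 in the low-kind and 0.05 in the high-kind runs). These genes were picked by the pooled ratio, which favours equal signs within the kinds. As differences of mean log2(TPM+1) all 24 were smaller, for example 0.85 for Spp1, 0.62 for Gnb5, -0.75 for Ifngr1 and -1.56 for Ugt2b34. Leaving out 1 run shrank 13 of them by over 1.5-fold, to -0.44 for Emd, 1.01 for Utp4 and 1.31 for Commd5 without the old cells 159 to 190, to 0.24 for Grtp1 without the old cells 139 to 158 and to 1.19 for H4c8 without the old cells 191 to 199. Among the lowest genes, the values were -1.01 for Gpr89, -1.18 for Stim2, -1.20 for Tmem231 and -1.59 for Fuca2 without the young cells 1 to 39, -2.02 for Etfrf1 and -1.73 for Tbc1d23 without the old cells 159 to 190, -3.53 for Ifngr1 without the young cells 55 to 86 and -2.42 for Ugt2b34 without the young cells 87 to 138.

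Over all 4749 genes with a mean TPM of 10 or above at either age, the ages were alike in level, with a Pearson r of 0.862 and a Spearman rho of 0.796 across genes, which are not independent replicates. The median log2 ratio was -0.08, and the 5th and 95th percentiles were -1.37 and 1.11. The age differences found in the low kind and in the high kind, which share no cells, had a Pearson r of 0.07 across these genes. Ribosomal protein genes had a median of 0.07, interferon and antigen presentation genes -0.05, lysosome and autophagy genes -0.15, splicing and transcription genes -0.19 and cytoskeleton genes -0.29. In the low and high kinds these medians were 0.05 and -0.18, 0.25 and -0.62, -0.21 and -0.40, 0.05 and -0.26 and -0.32 and -0.25. The cytoskeleton median lay at the 2.25 percentile of random lists over all cells and at the 9.37 and 10.5 percentiles in the low and high kinds.

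Old cells were about as different from each other as young cells were. The median Spearman rho between cells of one age was 0.372 in young and 0.356 in old cells. The median coefficient of variation over 3421 genes was 2.05 and 2.16, and the median log2 ratio of the coefficients was 0.05. Ins2 varied least among the genes looked at, with coefficients of 0.186 and 0.175, and the coefficient of Nupr1 was 2.64 in young and 1.76 in old cells. Within single runs the median rho lay between 0.372 and 0.422 in young and between 0.352 and 0.392 in old runs.

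Markers of cells outside the endocrine islet were mostly near 0. Markers of acinar, endothelial, erythroid and stellate cells all had means under 10 TPM at both ages. Krt7 and Clu, which were fixed as ductal markers, were at 86.1 against 114 TPM and 91.0 against 51.4 TPM, while Krt19 was at 0.06 TPM in young and listed at 0 in old cells. Macrophage markers were found together in few cells: 5 of 138 young (3.62%, 1.19 to 8.25%) and 1 of 69 old cells (1.45%, 0.0367 to 7.81%) had at least 3 of the fixed leukocyte markers at TPM 10 or above. Lyz2, a macrophage lysozyme gene, was at 159 against 9.13 TPM, with 48.4% of the young total in 1 cell, while Tyrobp, an adaptor gene of leukocyte receptors, was at 110.1 against 119 TPM, with 99.8% of the old total in 1 cell. Irx1, an alpha-cell regulator, had no cell at TPM 1 or above at either age, while Ttr was at 910.3 against 962 TPM. The Y-linked genes Ddx3y and Eif2s3y were detected in 50.0% and 53.6% of young and 40.6% and 34.8% of old cells.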

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

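Alternatives that weight or leave out runs, or leave out macrophage-marked cells or the highest cell of Pyy or Btg2, were chosen after seeing the data. List medians stayed within 1.5-fold of their main value without a changed sign in 364 of 374 cases. A sign was compared only if the main log2 value was at least 0.2 in size. Most list medians were themselves smaller than 1.5-fold, so this count is a weak check of them. It also leaves out the split by kind, where the disallowed medians were 0.75 and -0.52 and the immature medians 1.09 and -0.32 in the low and high kinds. Of 2713 values of the named genes, 2403 stayed within 1.5-fold without a changed sign, 281 moved by over 1.5-fold and 29 changed sign. Changed signs were counted for genes only where the main difference was at least 1.5-fold, so that smaller ones also crossed 0. The named genes that moved went 116 times to a larger and 165 times to a smaller size. The cause was not tested except where given. The median over all genes (-0.08) was -0.20 with means of log2(TPM+1), a shift of over 0.1, and between -0.17 and -0.0013 under the other alternatives fixed beforehand; the 95th percentile was 0.44 on that log scale. The cell cycle median was -2.45 and -0.51 with pseudocounts 0.1 and 5, -0.17 with means of log2(TPM+1) and -0.0936 with trimmed means, since its genes were rarely detected. The disallowed-gene median was 1.097 with matched young cells and -0.0029 with no filter, and the senescence median 0.0132 with members at TPM 10 or above. Leaving out each run in turn, medians ranged from -0.64 to 0.83 for disallowed, -0.18 to 0.54 for immature and -1.33 to -0.33 for immediate early genes. Median detected genes at TPM above 0 and at 10 or above were 6186.5 and 2311 in young and 5958 and 2146 in old cells, by construction. Cells with another hormone at TPM 100 or above were 47.8% of young and 59.4% of old cells, and 0 at TPM 10000 or above. Signs changed with means of log2(TPM+1) and trimmed means for Vim (0.21, 0.33), Cd74 (0.0176, 0.26) and H2-Aa (0.25, 0.84), and with trimmed means for Cdkn2c (-0.0272). With matched young cells they changed for Vim (3.29), C1qa (0.20), Cd74 (0.62) and H2-Aa (0.88), and without macrophage-marked cells for Tgm2 (-0.0296), C1qb (0.20), Cd74 (0.49) and H2-Aa (1.90). Leaving out each run changed the sign of Arpc3 (-0.0413 to 2.70), C1qa (-1.24 to 0.25), Ccnd3 (-0.0504 to 1.13), Cd74 (-6.56 to 0.0966), Emd (-0.44 to 2.31), Ern1 (-0.87 to 1.33), Ffar1 (-2.96 to 0.74), Gast (-0.21 to 1.75), H2-Aa (-5.05 to 0.50), Hspa1b (-3.06 to 1.38), Lmo4 (-0.64 to 1.73), Peg3 (-1.83 to 0.14), Rfx6 (-0.0503 to 1.49) and Vim (-1.80 to 1.32). Depth, which TPM hides, limits the values of genes seen in few cells. No paired analysis was possible because no test was made and replicate numbers only name cells.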

Other observations

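Of the tests below, those of runs and kinds of runs were chosen after the result was seen, and those of detected genes and of hormone scaling before.

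Old and young cells of 1 kind of run shared features that crossed the ages. The mitochondrial gene mt-Co1 was at 1313 TPM in young and 1367 TPM in old cells of the low kind and at 8970 and 11541 TPM in the high kind, while mt-Co3 was at 22124 and 33656 TPM in the low and 26774 and 35425 TPM in the high kind. Of the 94 cells of the low kind, 3 had a ratio of mt-Co1 to mt-Co3 nearer to the high kind, and of the 113 cells of the high kind, 6 had one nearer to the low kind. Mt-Co1 is a respiratory chain subunit gene like mt-Co3, and both are read from the same long mitochondrial transcript. Insulin took a median of 53.7% and 52.7% of TPM in young and old cells of the low kind and 55.1% and 50.9% in the high kind. The macrophage-marked cells held insulin transcripts as well, at 15.7 to 49.9% of TPM, with 3608 to 6506 detected genes. Whether these cells are doublets was not tested.

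Age differences over all genes were weighed against differences between runs. With 8 cells drawn from each run, the mean absolute difference of mean log2(TPM+1) between runs of different ages was 0.957 times that between runs of the same age (1.09 against 1.14). This ratio decided nothing, since 2 draws of 8 cells from 1 run already differed by 0.866, so sampling of cells made up most of each distance. Across genes, the age differences found in the 2 kinds had a Pearson r of 0.0714, below the 0.20 of the kind differences found in the 2 ages (-0.05 and 0.44 on means of log2(TPM+1)). The kinds were cut from these same data on a technical measure, which can favour shared kind differences. Age differences of single genes that were not seen in both kinds may reflect runs or the sampling of 29 to 84 cells per group. The share of sampling in these correlations was not measured, and an effect of age stays untested.

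The lower immediate early genes of old cells may in part reflect handling of single runs. Within the high kind their mean log2(TPM+1) was higher in both young runs (4.45 and 2.69) than in both old runs (1.61 and 1.74), but the young runs lay 1.76 apart, as far as the ages in that kind (-1.71). The span of 2.57 over all young runs, against -1.003 between the ages, mixes the kinds. The number of detected genes was not the cause by itself, since the median was -1.14 once young cells were matched to old cells on it. An unequal mix of the 2 kinds was not the whole cause either, since the median was -2.07 within the high kind, and an effect of age stays open.

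The higher mitochondrial coding transcripts of old cells stayed after rescaling without the hormone genes, and within both kinds. Rescaling left a median of 0.29 of the 0.41. Whether hormone scaling made the rest cannot be told from this, since a rise of mitochondrial transcripts itself lowers the hormone share. Hormone genes took a mean of 61.6% of TPM in young and 59.0% in old cells. Without rescaling, the median was 0.48 within the low kind and 0.40 within the high kind, and rescaling within the kinds was not done. Differences between runs of 1 kind remain a candidate explanation, because the old runs of the high kind lay 0.70 apart in mean log2(TPM+1), against 0.37 between the ages in that kind, where both old runs were above both young ones, and the runs of the low kind overlapped. The span of 0.80 over all young runs, against 0.24 between the ages, mixes the kinds. Cell quality, which can raise this share in damaged cells, and age were not separated by any value here.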
